A study of Homo sapiens with 8 samples.

How the data were processed

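HCC38 cells had been transfected, per the labels, with a negative control siRNA or a miR-449a mimic, and RNA was hybridised to single-colour Agilent arrays (Cy3). The 8 arrays fall into 4 control and 4 mimic arrays, numbered 1 to 4 in each group. Per the file headers, the scanner files came from Agilent Feature Extraction 11.0.1.1 on 1 slide in 1 scan, with experiments 1 and 2 in slide row 1 and experiments 3 and 4 in slide row 2. The deposited scanner files hold the processed signal and the pixel medians of spot and local background as intensity, not normalised between arrays. The deposited series matrix holds log2 values. From the values, the authors shifted each array by its 75th percentile and centred each probe on its median. The scanner values treated that way correlated with the matrix at r above 0.999 on each array. Their median absolute difference from it was 0.0071 to 0.0291 per array. The correlation does not depend on an array's shift, so only these differences bear on the percentile. The tool for the shift and centring is not stated.

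The deposited scanner file of control replicate 3 held another unit (other than plain intensity): it had been saved from a spreadsheet, and 62976 cells of the processed signal carried a decimal comma, 3 significant digits and a factor of 1e+06, which was divided out. The rounding amounts to at most 0.0072 on the log2 scale. In the median columns, 6404 cells had become dates, from which the original pixel values were restored.

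Log2 processed signals were averaged over the spots of each probe after spots marked as non-uniform or as population outliers had been left out, and each array's 75th percentile over non-control probes was subtracted. In 146 probes at least 1 array then had no value. Probes well above background on at least 4 of the 8 arrays, in whichever group, were kept, which left 31431 of 58201. RefSeq accessions on the probes were matched to gene symbols with the RefSeq table for GRCh38.p14, used for names alone: 31104 probes (53.4%) got a symbol, and those with Ensembl transcript or lncRNA identifiers did not, since no table paired them. The brightest probe by mean over all 8 arrays stood for each gene; 4349 genes had several kept probes, and none had probes called in opposite directions. This gave 25612 genes and unnamed transcripts, 16351 with a symbol. A gene not well above background in any control array is given as a lower bound, with its control values raised to the lowest signal well above background on each array.

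Mimic and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p below 0.05 over all genes tested). Files were read with the data.table package (version 1.17.8) and plots drawn in Python 3.11.15. The normalised arrays with the same number in both groups correlated at 0.323, 0.362, 0.551 and 0.649 after each group's mean had been removed. Arrays of unlike number correlated at -0.521 to 0.325. The highest of these, control 3 with mimic 2, was about as high as experiments 1 and 2, whose pairing is thus less clear. A fit with the experiment number as an additive block was run beside the unblocked fit. The 4 experiments' own log2 differences correlated with each other at 0.304 to 0.641, across genes that are not independent replicates. On simulated data of 25551 genes for this comparison, limma recovered 2.99% of 67 genes changed by 0.5 on the log2 scale, 50.7% of 67 changed by 1 and 81.8% of 66 changed by 2, with 0 false calls. With the block it recovered 16.4, 74.6 and 89.4%, with 2 false calls. The simulated residual noise was drawn separately for each gene and few genes were changed, so these shares need not hold for the real arrays.

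For 29 gene lists, camera tested the shift of each list of at least 5 tested genes against all other genes (preset correlation 0.01, two-sided, adjusted over the lists); it was repeated with an estimated correlation, and fry tested whether a list moved on balance in 1 direction. Counts per list were taken over all genes tested and adjusted over the list alone, and lists share up to 4 genes. Groups, tests, thresholds, lists, the 12 genes fixed in advance and the processing choices to vary were set before the data were examined. Named genes follow a rule: the 10 largest fitted rises and 10 largest falls among genes with a symbol that passed and moved the same way in all 4 experiments, up to 4 genes of smallest p from each list, and the 12 fixed genes (CCND1, CDK4, CDK6, CCNE2, CDC25A, E2F3, E2F5, HDAC1, MET, NOTCH1, SIRT1 and BCL2). Symbols beginning with LOC, XLOC, lnc or LINC were left out of the ranks of rises and falls. Names outside that rule are given as picked after their values were seen.

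The choices varied were normexp background correction (offset 50), quantile normalization, no filter on dim probes, probes well above background on all 8 arrays, the mean of a gene's probes, every probe on its own, the series matrix values, an intensity trend in eBayes, the block, the slide row as a term and each array left out in turn. A planned comparison of genes with and without a seed match in the 3′ UTR was left out, because no UTR sequences were given. Control probes were left out.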

Results

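RNA from HCC38 cells, an established line of triple negative breast cancer, was measured on 8 single-colour Agilent expression arrays. The cells had received a negative control siRNA for 4 arrays and a synthetic mimic of the microRNA miR-449a for the other 4. Both RNAs were given at 50 nM, and the cells were collected at 48 h. The labels number the experiments 1 to 4 in each group but do not say whether they came from separate cultures, so the p-values measure only the spread between these arrays. The 75th percentile of intensity lay between 415 and 552 per array, and 48.6 to 56.5% of 58201 probes were well above background. The number of arrays limits the precision of every value. The comparison asks which genes respond to the mimic, with DNA repair and the separation of chromatids named as the subjects of the study.

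Genes with names from cilia led the rises with the mimic among genes with a symbol that passed and rose in all 4 experiments. The largest, of DNAI3, was 2.68 ± 0.50 on the log2 scale (± SE, n = 4 against 4; limma, adjusted p = 0.0251), and SPEF1 followed with 2.66 ± 0.46, DNAI7 with 2.57 ± 0.46 and DNAH7 with 2.43 ± 0.45. KIF9 was not well above background in any control array, which makes its rise at least 3.91-fold. LRGUK rose at least 2.50-fold and DRC3 at least 2.02-fold on the same reckoning. PRR29 (2.37 ± 0.54), DIO2 (2.24 ± 0.46) and FBXO36 (2.23 ± 0.33) completed the 10 largest fitted rises, a rank that for KIF9, LRGUK and DRC3 rests on control values near background. DNAI7 and DNAH7 were well above background in only 2 of the 4 control arrays, so their differences and ranks rest in part on such values too. Among the falls, RTL8B changed by -1.66 ± 0.13 (limma, adjusted p = 0.00275), MYB by -1.60 ± 0.14 (0.00356), SGPP1 by -1.58 ± 0.20 and GINS3 by -1.43 ± 0.21. The other falls among the 10 largest ran from DYNC1I1 (-1.39 ± 0.18) over ELMOD1, E2F2, NUP210 and RBPMS2 to FOXN3 (-1.32 ± 0.19).

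Over 25612 genes and unnamed transcripts tested with limma, 392 were higher and 697 lower with the mimic, of which 99 and 79 changed at least 2-fold. Of all these calls, 300 higher and 553 lower were genes with a symbol. With the experiment number as a block, 2028 were higher and 2628 lower, 195 and 111 of them at least 2-fold, and all 1089 calls of the unblocked fit were among them. Each array mattered to these counts. Without control replicate 1, 2, 3 or 4 the higher calls numbered 72, 70, 216 and 189, and the lower calls 138, 118, 404 and 360. Without mimic replicate 1, 2 or 3 they numbered 122, 79 and 112 higher and 264, 164 and 266 lower, and without mimic replicate 4 there were 1083 higher and 1629 lower. Of 76 named genes past the threshold, 18 stayed past it whichever array was left out, among them KIF9, LRGUK, DRC3, RTL8B, MYB, SGPP1, DYNC1I1, CDK6, TK1, BIRC5 and EME1. The other 58 lost the call in at least 1 of the 8 fits, and several of them in most. DNAI3 passed in only 2 of the 8 (limma, adjusted p = 0.0872 without control replicate 1), as did DNAI7, DNAH7, PRR29 and DIO2. E2F3, KRT7, ESRP2 and SNAI1 passed in only 1. No named gene changed direction. Within slide row 1, which held experiments 1 and 2, 416 genes were higher and 516 lower. Within slide row 2, which held experiments 3 and 4, limma called 0, with 854 at an unadjusted p under 0.05.

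**Figure D1:**
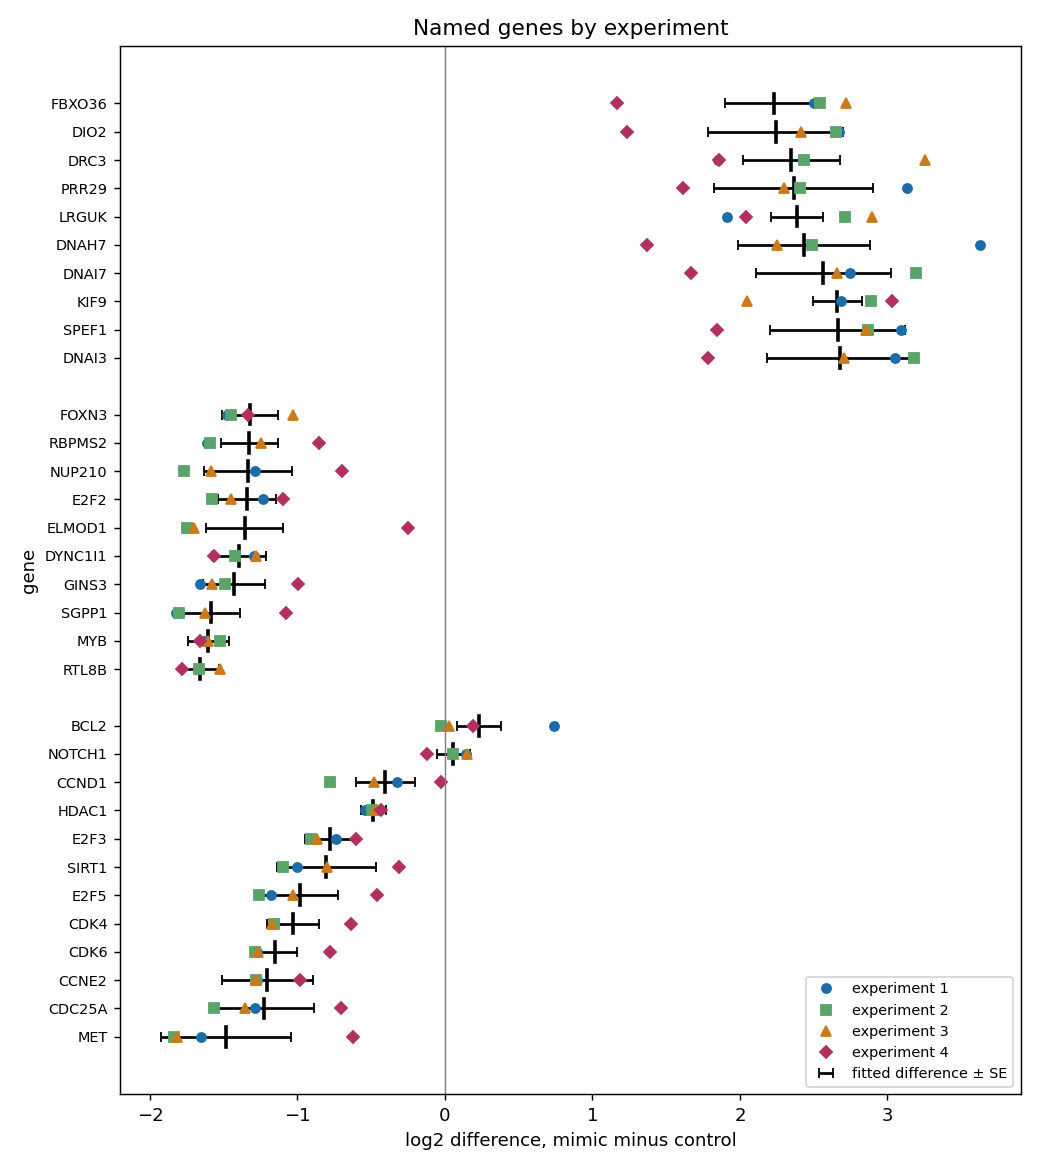
Log2 difference between mimic and control (horizontal axis) for the 10 largest fitted rises, the 10 largest falls and 12 genes fixed in advance (vertical axis), with symbols for the 4 experiments and bars for the fitted difference ± SE over 4 arrays per group. DNAI3 stands at 2.68 and RTL8B at -1.66, while BCL2, at 0.23, and NOTCH1, at 0.06, lie near 0 and did not pass the test.

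Published targets of the miR-34/449 family, whose members share a seed sequence, were lower with the mimic. CDK6 fell by 1.15 ± 0.15 on the log2 scale (limma, adjusted p = 0.0088), CDK4 by 1.03 ± 0.18 (0.0192), E2F3 by 0.78 ± 0.17 (0.0427) and HDAC1 by 0.49 ± 0.08 (0.0208). RRAS (-1.23 ± 0.18), LDHA (-0.59 ± 0.10) and SNAI1 (-0.45 ± 0.09) were also lower. Of the 27 listed targets tested, 7 were lower over all genes tested, 15 when adjusted over the list alone and 14 with the experiment as a block; none was higher in any of these counts. The list's median was -0.57 (camera, adjusted p = 4.7e-10, and adjusted p = 0.352 with an estimated correlation), and it ran from -0.80 to -0.31 over the experiments.

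Of the 12 genes fixed in advance, 8 did not pass. MET (-1.48 ± 0.44; limma, adjusted p = 0.0993), CDC25A (-1.23 ± 0.34; 0.0852), CCNE2 (-1.20 ± 0.31; 0.0686), E2F5 (-0.98 ± 0.26; 0.0723) and SIRT1 (-0.80 ± 0.33; 0.224) passed with the experiment as a block, at adjusted p values of 0.0142, 0.00924, 0.00644, 0.0140 and 0.0209. Without mimic replicate 4 these 5 genes passed too, with the highest adjusted p, 0.0314, for SIRT1. CCND1 stood at -0.40 ± 0.20 (0.318; 0.0880 with the block) and passed only without mimic replicate 4 (0.0384). NOTCH1 (0.06 ± 0.11; 0.849) and BCL2 (0.23 ± 0.15; 0.444) passed in none of these fits.

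On the list of sister chromatid cohesion and separation, 32 of 38 differences were negative and 6 positive. The falls were led by the condensin subunits NCAPH (-0.81 ± 0.09, limma, adjusted p = 0.00579), NCAPG (-0.68 ± 0.11) and NCAPD2 (-0.73 ± 0.12) and by the anaphase-promoting complex subunit CDC23 (-1.12 ± 0.13). Separase (ESPL1, -0.71 ± 0.13) and securin (PTTG1, -0.61 ± 0.13) fell as well, and both were picked out after their values were seen. Of 38 genes on the list of cohesion and separation, 8 were lower over all genes tested, 20 adjusted over the list alone and 23 with the experiment as a block, and none was higher. The median was -0.42, and between -0.49 and -0.36 in every experiment (camera, adjusted p = 6.41e-10, and adjusted p = 0.387 with an estimated correlation).

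Spindle and kinetochore genes were lower as well. SPC25 changed by -0.96 ± 0.12, BIRC5 by -0.77 ± 0.10 and HMMR by -0.97 ± 0.13 (limma, adjusted p = 0.00885 each), and CENPI by -0.76 ± 0.11. All 42 genes on this list had a negative difference, with 21 past the threshold over all genes tested, 38 adjusted over the list alone and 41 with the block. Their median was -0.66 (camera, adjusted p = 1.12e-25, and adjusted p = 0.352 with an estimated correlation). Among regulators of the G2 to M transition, CDC25C (-0.78 ± 0.10), WEE1 (-0.67 ± 0.09), HMGB2 (-0.77 ± 0.13) and PIMREG (-0.62 ± 0.10) were lower. All 30 had a negative difference, with 15 past the threshold over all genes tested, 27 adjusted over the list alone and 28 with the block, and a median of -0.63 (camera, adjusted p = 2.25e-20, and adjusted p = 0.352 with an estimated correlation).

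Homologous recombination genes were lower, with EME1 at -0.77 ± 0.09 (limma, adjusted p = 0.00687), BRCA1 at -0.83 ± 0.17 (0.0306), RMI2 at -0.74 ± 0.15 and GEN1 at -0.63 ± 0.14. BLM (-0.94 ± 0.21) also fell, and was picked out after its values were seen. Of 38 genes, 6 were lower over all genes tested, 21 adjusted over the list alone and 27 with the experiment as a block. The median was -0.52 (camera, adjusted p = 5.47e-12, and adjusted p = 0.423 with an estimated correlation; fry, 0.0535, or 0.00905 with the block). BRCA1 lost its call without control replicates 1, 2 and 4 and without mimic replicates 1, 2 and 3, at adjusted p values up to 0.106.

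In the Fanconi anaemia and crosslink repair list, FANCG fell by 0.95 ± 0.14, FANCD2 by 0.98 ± 0.17, FANCC by 0.63 ± 0.10 and FANCL by 0.46 ± 0.10. FANCI, picked out after its values were seen, fell by 0.78. Over all genes tested 5 of 19 were lower. Adjusted over the list alone 8 were lower and 1 higher, and with the block 12 were lower and 1 higher. The median was -0.37 (camera, adjusted p = 1.67e-04, and adjusted p = 0.415 with an estimated correlation). Among 18 genes of non-homologous end joining, MDC1 (-0.46 ± 0.09; limma, adjusted p = 0.0291) was the single one past the threshold, against 4 lower adjusted over the list alone and 7 lower and 1 higher with the block. Its median of -0.29 passed camera (adjusted p = 0.0276, and adjusted p = 0.597 with an estimated correlation) but not fry (0.157), which passed with the block (0.0111). The camera call was lost without control replicate 1 (0.063), control replicate 4 (0.0805), mimic replicate 2 (0.0595) or mimic replicate 3 (0.0951).

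Excision and mismatch repair genes moved apart. DDB2 fell by 0.77 ± 0.09 (limma, adjusted p = 0.00573) and RAD23B by 0.59 ± 0.13, whereas ERCC2 rose by 0.59 ± 0.10 (0.0209). Over all genes tested 5 of 34 were lower and 1 higher. Adjusted over the list alone 8 were lower and 2 higher, and with the block 10 were lower and 3 higher. The list's median of -0.05 did not pass camera (adjusted p = 0.143, and adjusted p = 0.762 with an estimated correlation), except without control replicate 3 (0.0450), and passed fry with the block (0.00905).

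Replication and G1/S genes had the most negative median of the 29 lists. TK1 changed by -1.16 ± 0.11 (limma, adjusted p = 0.00376), E2F2 by -1.34 ± 0.20 and GINS1 by -0.65 ± 0.09. All 42 had a negative difference, with 12 past the threshold over all genes tested, 35 adjusted over the list alone and 37 with the block. The median was -0.70 (camera, adjusted p = 3.6e-20, and adjusted p = 0.387 with an estimated correlation). Replication-dependent histone genes, whose near-identical copies the probes may not tell apart, were lower too, with H4C2 at -1.05 ± 0.19, H4C13 at -1.12 ± 0.21, H4C3 at -0.98 ± 0.20 and H2AC20 at -0.96 ± 0.20, and with H4C5 (-0.84), picked out after its values were seen. Of 31 tested, 5 were lower over all genes tested, 13 adjusted over the list alone and 17 with the block, around a median of -0.33 (camera, adjusted p = 4.83e-09, and adjusted p = 0.352 with an estimated correlation).

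**Figure D2:**
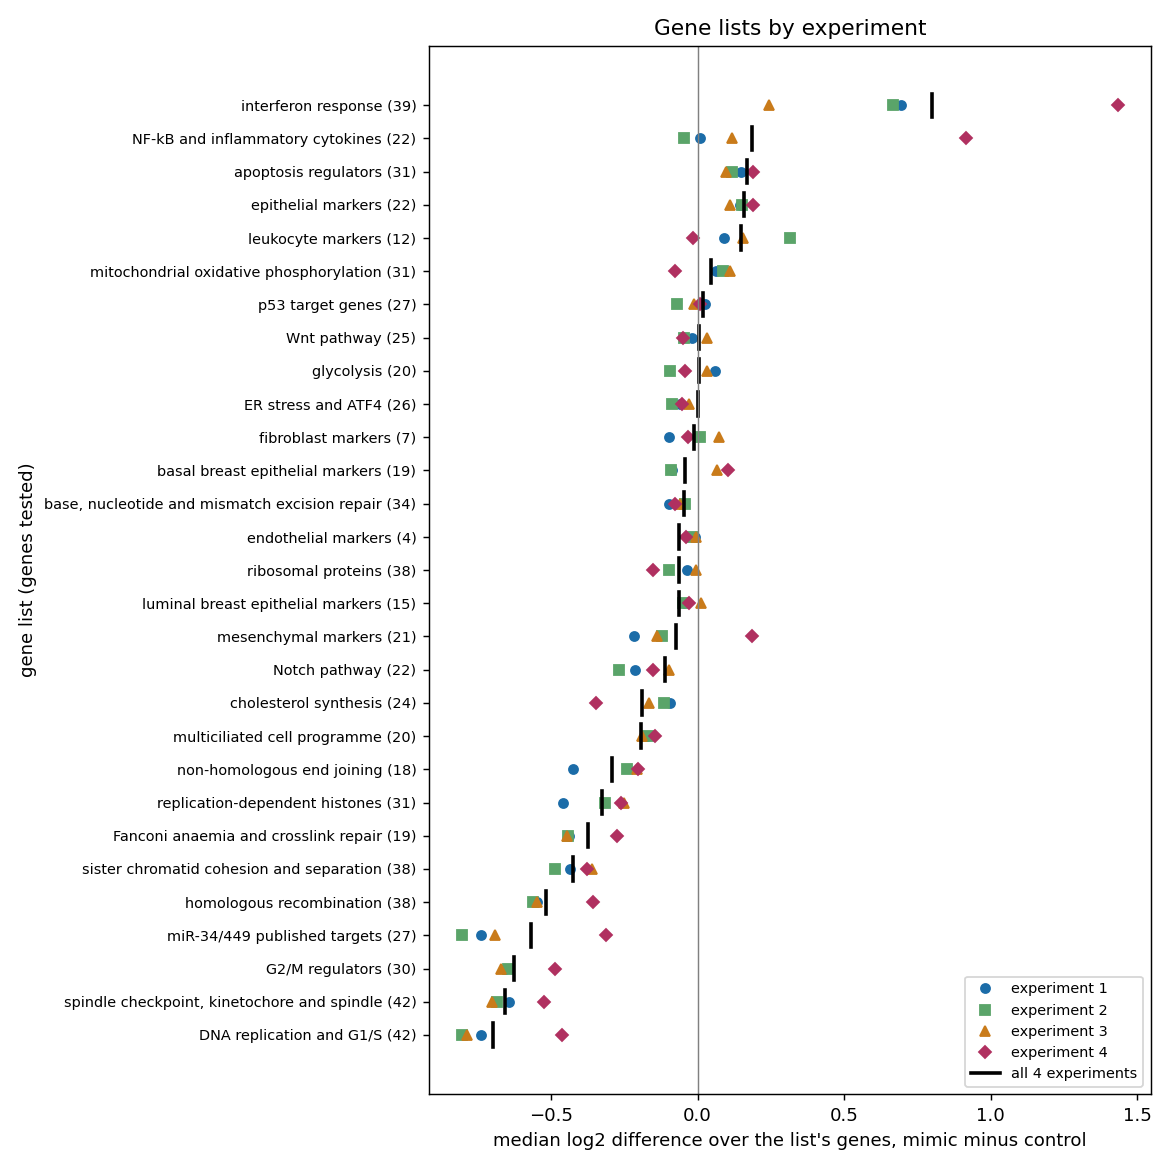
Median log2 difference between mimic and control over the tested genes of each list (horizontal axis) for 29 lists (vertical axis, with the number of genes tested), with symbols for the 4 experiments and a bar for the median of the fitted differences. The lists of replication (-0.70), spindle (-0.66) and G2/M genes (-0.63) lie farthest to the left in the fit of all arrays, and the interferon response (0.80) farthest to the right.

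Interferon response genes were higher on the mimic arrays, with OAS2 at 1.40 ± 0.30 (limma, adjusted p = 0.0383) the single one of 39 past the threshold over all genes tested and adjusted over the list alone. MX1 was 2.96-fold, IRF9 2.15-fold and STAT2 1.44-fold higher, with SEs of 0.41, 0.31 and 0.15 on the log2 scale. These genes had adjusted p values of 0.0697, 0.0836 and 0.0857, and of 0.00644, 0.00687 and 0.0247 with the experiment as a block. With the block, 22 genes of the list passed, all higher. The median was 0.80, with 36 of 39 differences positive (camera, adjusted p = 2.24e-08, and adjusted p = 0.597 with an estimated correlation; fry, 0.294, or 0.0204 with the block). By experiment the median was 0.69, 0.67, 0.24 and 1.43. In experiment 4 both arrays were high: relative to the control means, control replicate 4 stood at 0.81 and mimic replicate 4 at 2.31, against -0.27 to -0.25 in the other controls and 0.19 to 0.46 in the other mimic arrays. OAS2 kept its call only without control replicate 4 or mimic replicate 4, with adjusted p values up to 0.123 when another array was left out.

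**Figure D3:**
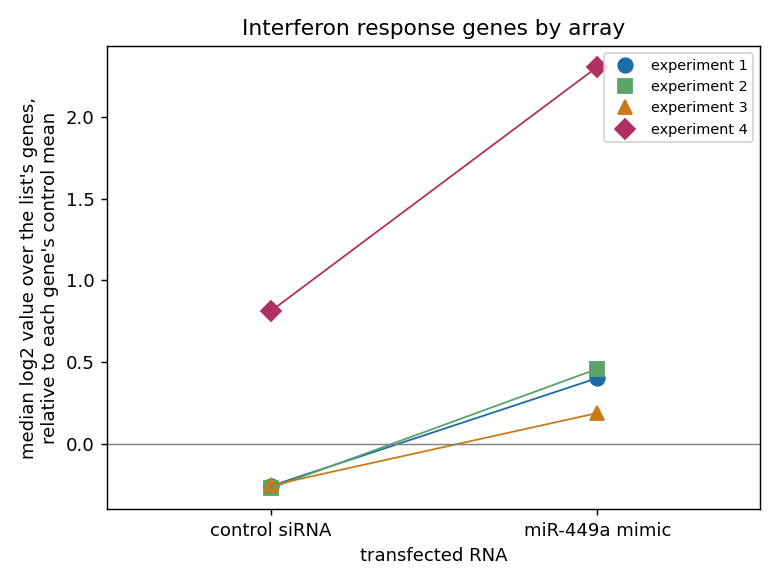
Median over 39 interferon response genes of the log2 value relative to each gene's control mean (vertical axis) on each array, by transfected RNA (horizontal axis), with symbols for the 4 experiments and lines joining arrays of the same number. Every line rises, and both arrays of experiment 4 (0.81 and 2.31) lie above all other arrays.

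In the list of NF-kB and inflammatory cytokine genes, 0 of 22 passed limma over all genes tested or adjusted over the list alone, and 4 were higher with the block. Its median was 0.19, and 0.91 in experiment 4 (camera, adjusted p = 0.244, or 0.0383 with the block, and adjusted p = 0.833 with an estimated correlation). Camera passed without control replicate 4 (0.00176), mimic replicate 2 (0.0309) or mimic replicate 3 (0.0298), and with no filter on dim probes (0.0354).

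Of the epithelial markers, KRT7 rose by 0.47 ± 0.08 (limma, adjusted p = 0.0236) and ESRP2 by 0.39 ± 0.09, and 14 of 22 differences were positive. Here 2 of 22 passed over all genes tested, 4 adjusted over the list alone and 8 with the block, all higher (median 0.16; camera, adjusted p = 0.0148; adjusted p = 0.387 with an estimated correlation). Among mesenchymal markers SNAI1 was the single call in 21 genes, with 2 lower adjusted over the list alone, and 4 lower and 1 higher with the block (median -0.07; camera, adjusted p = 0.609). Of 19 basal breast markers, ITGA6 (-0.80 ± 0.12) was lower by both counts, and with the block 1 was lower and 2 higher (camera, adjusted p = 0.609). For luminal markers 1 of 15, XBP1 (-0.53 ± 0.09), was lower by both counts, and 2 lower and 1 higher with the block (camera, adjusted p = 0.667). None of these 3 lists passed with an estimated correlation (adjusted p = 0.762, 0.780 and 0.766).

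In the Notch pathway list, NUMBL (-0.73 ± 0.09), HEYL (-0.42 ± 0.09) and HEY1 (-0.93 ± 0.19) were lower, while 8 of the 22 differences were positive. Of 22 genes 3 were lower over all genes tested, and 6 lower and 1 higher adjusted over the list alone, against 8 and 1 with the block. The median was -0.11 (camera, adjusted p = 0.036, and adjusted p = 0.387 with an estimated correlation), and the camera call was lost without control replicate 4 (0.087), mimic replicate 2 (0.114) or mimic replicate 3 (0.0632). Normexp (0.0757), probes well above background on all 8 arrays (0.0623) and named genes alone (0.0564) lost it too. In the Wnt list, WNT5B rose by 1.88 ± 0.28 and FZD2 fell by 0.41 ± 0.09, the 2 calls among 25 genes by both counts. The block added 2 higher. Its median was 0.01 and its mean 0.10, but camera gave a downward direction (adjusted p = 0.978, and adjusted p = 0.979 with an estimated correlation).

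The fixed list of the multiciliated cell programme moved apart: RSPH1 rose by 1.98 ± 0.37 and MYB fell, while the other 18 of 20 did not pass over all genes tested or adjusted over the list alone. With the block 4 were higher and 6 lower. The median was -0.19 and camera did not pass (adjusted p = 0.387, and adjusted p = 0.597 with an estimated correlation), while fry did, in the downward direction (0.0365).

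Among apoptosis regulators, BAK1 rose by 0.39 ± 0.08 as the single call in 31 by both counts, and with the block 4 were higher and 1 lower. The median was 0.17 (camera, adjusted p = 0.0399, and adjusted p = 0.425 with an estimated correlation), and the camera call was lost without control replicate 1 (0.0884), control replicate 2 (0.102) or mimic replicate 4 (0.304). The mean of probes (0.0506) lost it, and so did leaving out experiment 4, unblocked (0.0986) or blocked (0.0512). In the p53 target list SESN1 (-0.44 ± 0.08) and DDB2 were lower, 2 of 27 over all genes tested and 3 adjusted over the list alone, against 3 lower and 2 higher with the block. Its median was 0.02, its mean -0.01 and the direction of camera down (adjusted p = 0.978, and adjusted p = 0.979 with an estimated correlation). ER stress genes gave XBP1 lower and HSPA5 (0.35 ± 0.08) higher among 26, with 2 lower and 1 higher adjusted over the list alone and 3 and 2 with the block. The median was 0.00, the mean -0.01 and the direction of camera down (adjusted p = 0.609, and adjusted p = 0.762 with an estimated correlation).

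Cholesterol synthesis genes had a median of -0.19, and 0 of 24 passed limma over all genes tested, 3 were lower adjusted over the list alone and 7 with the block. Camera passed (adjusted p = 0.0148, and adjusted p = 0.762 with an estimated correlation) but not without control replicate 3 (0.137), mimic replicate 4 (0.304) or the whole of experiment 4 (0.0875). Ribosomal protein genes, 0 of 38 by both counts and 1 lower with the block, had a median of -0.06 (camera, adjusted p = 0.0435, and adjusted p = 0.766 with an estimated correlation). That call was lost without control replicate 1 (0.139), control replicate 2 (0.166), mimic replicate 3 (0.077) or mimic replicate 4 (0.491). It was also lost with quantile normalization (0.653), normexp (0.170), no filter (0.0993), probes well above background on all 8 arrays (0.0700), the mean of probes (0.102), named genes alone (0.0627), and without experiment 4, unblocked (0.233) or blocked (0.168). Oxidative phosphorylation gave 0 of 31 by both counts, 2 higher with the block and a median of 0.05 (camera, adjusted p = 0.0938, and adjusted p = 0.763 with an estimated correlation), and passed without mimic replicate 4 (0.00961). It also passed with quantile normalization (0.00467), normexp (0.0104), no filter (0.0213), the intensity trend (0.0494), and without experiment 4, unblocked (0.0196) or blocked (0.0240). Of 20 glycolysis genes LDHA was the single call by both counts, with 2 lower and 1 higher in the blocked fit. The median was 0.00, the mean -0.03 and the direction of camera down (adjusted p = 0.609, and adjusted p = 0.780 with an estimated correlation).

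Few markers of other cell types differed between the groups. Of those on the arrays, 12 of 18 leukocyte, 7 of 12 fibroblast and 4 of 11 endothelial markers passed the background filter. Of 12 leukocyte markers tested none passed over all genes, CSF1R (-1.48 ± 0.34; limma, adjusted p = 0.0502) was lower adjusted over the list alone (0.0257), and 2 were higher and 1 lower with the block (median 0.15; camera, adjusted p = 0.516; adjusted p = 0.766 with an estimated correlation). Of 7 fibroblast markers 0 passed by both counts, and 1 was higher and 1 lower with the block. The median was -0.01, the mean 0.02 and the direction of camera down (adjusted p = 0.978, and adjusted p = 0.979 with an estimated correlation). Of 4 endothelial markers 0 passed by both counts and 1 was higher with the block, with too few genes for camera.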

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

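The fits without experiment 4 were chosen only after the values of that experiment had been seen; the other tests named here were set before their results were known. In 217 groups of 4 values (a gene, an array measure or a list's median within a group), 16 had a highest or lowest value standing apart by Dixon's test at the 95% level, the gap to its neighbour being given as a ratio to the whole range. Chance gives about 1 in 20 such groups, or 10.9 here, but 13 of the 16 lie in experiment 4. The groups share the same 8 arrays, and 76 of the 90 genes had passed limma. They are neither independent nor unselected, so 10.9 is only a rough guide.

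Among single genes on control arrays, replicate 4 stood apart for MX1 (5.68 against a mean of 4.22 in the others, log2 relative to the 75th percentile; ratio 0.885), IRF9 (2.67 against 1.48; 0.888), FOXN3 (-2.08 against -1.56; 0.858) and FANCC (2.30 against 2.52; 0.831). Control replicate 3 stood apart for CDK6 (4.10 against 4.26; 0.935) and control replicate 3 for MCIDAS (-4.36 against -3.49; 0.898). On the mimic arrays, replicate 4 stood apart for DNAI3 (-1.37 against 0.72; 0.870), SGPP1 (-2.09 against -2.89; 0.836), DDB2 (3.44 against 3.34; 0.915) and OAS2 (3.20 against 2.45; 0.874). Control replicate 4 also had the smallest share of probes well above background (48.6% against 54.3%; 0.831).

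Among the differences by experiment, experiment 4 stood apart for homologous recombination (-0.36 against -0.55; ratio 0.926), Fanconi anaemia genes (-0.28 against -0.44; 0.963), G2/M regulators (-0.49 against -0.66; 0.867) and NF-kB genes (0.91 against 0.03; 0.8292). Experiment 1 stood apart for non-homologous end joining (-0.42 against -0.22; 0.833).

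Interferon response genes were higher with the mimic in each experiment, most in experiment 4, where the control array was also high. A signal from experiment 4 alone is argued against: with the experiment as a block and without experiment 4, 22 of 39 genes were higher and 1 lower, with a median of 0.59. Spread between arrays stays open as an explanation, since 6 of the 35 splits of the arrays into 4 and 4 gave an absolute median as large as the real 0.80, and the highest other gave 1.23; of the 8 splits that part every pair of like number, the real one alone did, but 8 are too few for a share under 0.05. A response to the mimic is a candidate explanation consistent with the blocked values, and so is a response to transfected double-stranded RNA that differs between the preparations. No untransfected arrays were among the samples, so these cannot be weighed further.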

How the results depend on the processing

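Leaving out experiment 4 and testing named genes alone were chosen after seeing the data; the other alternatives were chosen before. No list or named gene that passed turned its direction under any of these alternatives. Of the 1089 calls, 4 outside the named genes changed sign when a gene's probes were averaged. Lower calls made up 55.2 to 70.4% of all calls over the settings. Counts of higher and lower genes, and of those changed at least 2-fold, stayed within 1.5 times with quantile normalization, all 8 arrays above background, the mean of probes, every probe, the series matrix, the intensity trend, the slide row term and named genes alone. Normexp, run on the spot medians because the files lack spot means, left the counts of calls within that range but gave 37 higher and 41 lower at least 2-fold; its offset shrinks differences of dim genes. With no filter on dim probes, 70 were higher and 109 lower (57 and 47 at least 2-fold), with 47752 genes tested in place of 25612. Only 160 of the 1089 calls were kept, and 52 of the 76 named genes past the threshold lost theirs. Lower calls went from 21 to 3 in the spindle list, 15 to 1 in G2/M, 12 to 3 in replication and 5 to 0 in Fanconi anaemia. The medians of these lists stayed the same.

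With the replicate block, 2028 were higher, 2628 lower and 195 at least 2-fold higher; the block takes out the spread that paired arrays share, and it kept all 1089 calls. Without experiment 4 the counts were 974 higher and 1406 lower (200 and 159 at least 2-fold), and with the block in addition 2559 and 3153 (229 and 180). With each array left out in turn they ranged from 70 to 1083 higher, 118 to 1629 lower, 40 to 198 at least 2-fold higher and 33 to 179 lower. The cause was not tested, neither for the low end nor for the higher counts without mimic replicate 4 or experiment 4.

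Of the 28 lists tested, 15 passed camera with the preset correlation, 12 to 15 with an array left out, and 0 with an estimated correlation, blocked or not. With an estimated correlation, the adjusted p values of camera were 0.352 for the published targets, the spindle and the G2/M lists. They were 0.387 for cohesion and for replication, 0.423 for homologous recombination, 0.415 for Fanconi anaemia and 0.597 for end joining and for interferon. With the block in addition these were 0.357 for targets and end joining, 0.311 for cohesion, spindle, Fanconi anaemia and G2/M, 0.355 for homologous recombination and replication, and 0.361 for interferon. The estimate adds the genes' joint spread, which the preset value leaves out. Fry in place of camera lost 6 lists, homologous recombination (0.0535), end joining (0.157), interferon (0.294), cholesterol (0.360), ribosomal proteins (0.388) and apoptosis (0.0592), and gained the multiciliated list (0.0365). Fry with the block passed the first 3 of these lists (0.00905, 0.0111 and 0.0204) and apoptosis (0.0105) but not cholesterol (0.0553) or ribosomal proteins (0.0925). It also passed excision repair (0.00905), ER stress (0.0384), luminal markers (0.0444) and the multiciliated list (0.0153), which camera did not; the cause was not tested. With each array left out, end joining ranged from 0.00273 to 0.0951 and excision repair from 0.0450 to 0.373. With camera and the preset correlation, the block changed 1 call, that of the NF-kB list (0.0383). The planned test of seed matches in 3′ UTRs was not run, for want of sequences. Signal over background limits the rises of KIF9, LRGUK and DRC3, which have lower bounds only.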

Other observations

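The list of cilium genes by symbol, its comparison with lists of like brightness, and the tests on 68 cilium genes and on 261 division and repair genes were chosen only after the values had been seen; the other tests were set before their results were known.

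With limma, the real split of the 8 arrays gave 1089 genes past the threshold, and the highest of the other splits gave 0. Thus 1 of 35 splits gave as many. The split following the slide rows gave 0. Among the 8 splits that part every pair of like number the highest other was also 0, but 8 are too few for a share under 0.05, here and for the sets of genes. The others leave some pairs together, so differences between experiments enter their comparison. The splits therefore cannot exclude chance.

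Genes whose symbols name parts of motile cilia were higher as a set. Outside the 10 largest fitted rises, which prompted the list, 68 were tested, with 18 higher and 0 lower (36 and 2 with the experiment as a block), a median of 0.48 and 3 members on the fixed multiciliated list; of 23 IFT and BBS genes, 4 were higher, with a median of 0.26. A rise shared by genes of like brightness is argued against, since the median of the 68 lay at percentile 100 of 10000 lists matched on mean expression, which spanned -0.15 to 0.19. Over all splits, 1 of 35 was as large for the 68 genes (0.48, highest other 0.43, and 0.28 among the 8 parting every pair). Spread between arrays is not excluded, since the 8 splits parting every pair are too few. Both comparisons used the arrays whose rises prompted the list, so neither is independent of that choice. Signal near background stays open. Of all 73 cilium genes, 50 were well above background on every array, among them DNAI3 and SPEF1 of the 10 largest rises. With normexp, these 50 had a median of 0.28 (quartiles 0.04 and 0.53, 43 of 50 positive). That is just short of the bound of 0.3 set for excluding it. A ciliary programme set off by the mimic is a hypothesis. The multiciliated list fixed in advance did not rise. Its median was -0.19, and it did not pass camera (adjusted p = 0.387) but passed fry in the downward direction (0.0365). With the block, 4 of its genes were higher and 6 lower. FOXJ1 (0.55, limma adjusted p = 0.199) and MCIDAS (-0.58, 0.229), picked out after the values were seen, did not pass, though FOXJ1 did without mimic replicate 4 (0.77, 0.0129).

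Genes of cell division and DNA repair were lower as a set, with a median of -0.54 over 261 genes of 8 lists. The lists' own medians ran from -0.70 for replication to -0.29 for end joining and -0.05 for excision repair. Scaling of the arrays is argued against, since quantile normalization left a median of -0.53 (quartiles -0.68 and -0.24) with 227 negative and 34 positive, and of -0.59 over the 209 genes of the 6 lists without those 2. Over all splits, 1 of 35 was as large for the 261 genes (0.54, highest other 0.47, and 0.35 among the 8 parting every pair) and for the 209 (0.62, highest other 0.51). Spread between arrays is not excluded, since the 8 splits parting every pair are too few. Fewer cycling cells at 48 h and a direct action of the mimic on these genes are each a candidate explanation; neither was tested, since the arrays hold no measure of cell cycle phase and no 3′ UTR sequences were given.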
